A study of Caenorhabditis elegans with 4 samples.

How the data were processed

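RNA of wild-type Caenorhabditis elegans at the L4 stage, the last larval stage, was measured on 4 arrays with 2 channels each. Per the labels, channel 2 of each array held 1 of 4 preparations of L4 RNA and channel 1 held wild-type mixed reference RNA. The composition of the reference, the dyes, the scanner, the background correction and the normalization are not given in the sources used here. The 4 arrays form 1 group. Nothing in the labels says that the preparations came from separate cultures, so the spread between these 4 samples may be partly technical. The p-values rest on that spread, with each gene's variance drawn toward a value common to all genes.

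The deposited table holds 1 value per probe and array for 21632 probes, and the authors gave no unit for it in the sources used here. The deposited values were read as log2 ratios between the channels. The basis is that 2 raised to a value fell on a grid of 0.001 for 100% of the values below 0 on each array, with a tolerance of 0.02 grid steps. Read as natural logarithms, 5.4% to 5.9% of the same values fell on that grid, and read as base-10 logarithms 3.7% to 4.3% did. The medians of the 4 columns as deposited were -0.047, 0.007, -0.1 and -0.042 for preparations 1 to 4. Whether the authors had centred the arrays is not stated. The direction of the ratio is not stated. Signs were kept as deposited, and a positive value is called likely higher in L4, because the labels describe each array as L4 against the reference, with L4 in channel 2. A test of the sign is in the closing section.

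Each array was centred on its median over probes. Of the probes, 16450 named 1 gene in the platform annotation, 247 named several and 4935 named none. Of the probes with 1 gene, 16365 matched a table of gene names from assembly WBcel235, and 0 symbols needed updating. That table was used for names only, and no coordinates are given because no genome build is named for the array. Probes of the same gene were averaged on each array, and probes with several genes or none stayed separate and unnamed. A probe or gene needed a value on at least 3 of the 4 arrays, which left 19910, of which 14900 were named genes. Among 329 called genes with more than 1 probe, the probes of 13 differed in sign.

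The mean log2 ratio was tested against 0, two-sided, with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, and p-values were adjusted by Benjamini-Hochberg at a threshold of 0.05. The reference RNA was the comparator and counts as 1 sample, so the test leaves out its own spread. The standard error (SE) given with a mean is limma's moderated one, and the SD is the plain SD over arrays. The moderation had 5.15 prior degrees of freedom. For genes that varied widely between arrays, the SE and the p-value are therefore smaller than the gene's own SD would give. An example is vit-2, with an SD of 1.95 and an SE of 0.62 over 4 arrays. Gene lists, 28 in all, were tested with limma's camera at a preset correlation of 0.01 and adjusted over the lists. Missing values were set to the mean of the other arrays in that step. Each list was tested again with the correlation estimated from the data, and with fry, which asks whether a list's genes move on balance one way without comparing them with other genes. The test with an estimated correlation was stricter for more than the correlation. For cytochrome P450, glutathione transferase and UDP-glucuronosyltransferase genes the estimate was 0.01, the preset value. Yet camera's unadjusted p rose from 6.93e-07 to 0.0199. Failing it therefore does not by itself show that a list owes its shift to correlated genes. Other lists had much higher estimates, at 0.95 for major sperm proteins, 0.96 for yolk and 0.82 for oocyte and eggshell genes. For such lists the part played by correlation was not separated from the stricter test. Some lists share members: bli-1, bli-2, col-7, col-19, col-62 and col-63 are both collagens and adult markers, and hsp-12.3 and hsp-12.6 are both heat shock and dauer genes. Other calculations used Python 3.11.15 with pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

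The tests, the lists, the alternatives and the rule for naming genes were fixed before the data were examined. The rule took genes that passed the threshold with a value on all 4 arrays and the same sign on all 4. It named the 12 highest and the 12 lowest means, with at most 3 genes of one symbol stem in each direction. It then named 4 further genes in each direction with a symbol of letters, hyphen and number. From each list it took up to 4 passing members with the largest absolute mean, or, where fewer than 2 passed, the 2 members with the largest absolute mean as well. The 6 genes with the highest SD between arrays were also named. Genes named outside this rule are marked as such.

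The calculation was tested on simulated data for the comparison of L4 with the reference over 19910 probes and genes, with 200 genes changed by known amounts. With variances drawn from the fitted prior, limma recovered 1% of genes changed by 1 on the log2 scale and 67% of those changed by 2, and 2.7% of its calls were false. With variances set to each gene's shrunken estimate, it recovered 32% and 98%, and 11.2% of its calls were false, above the nominal 5%. The first simulation was added after the second had been seen. Camera called the 1 shifted list in both, and 1 unshifted list in the second, where it called 2. The simulated genes were independent of each other, which the real ones are not. Changed genes were also a far smaller share than the 21.7% called in the data, which makes the Benjamini-Hochberg cutoff stricter in the simulation. The recovered and false shares therefore do not carry over to the data.

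The alternatives were values as deposited, arrays scaled to one spread, other minimum numbers of arrays, probes kept apart, robust variance shrinkage, a test against a 1.5-fold change, a threshold of 0.01, other list tests and leaving out each array in turn. A planned comparison of the X chromosome with the autosomes was not made, because no genome build is named and the gene table served for names only. Spot intensities were not used here, so the signal behind a ratio is unknown and the number of arrays limits the precision. Probe sequences were not used here either. Near-identical members of families such as the major sperm proteins, histones, collagens and chemoreceptors may hybridise to each other's probes, so values of single members are uncertain.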

Results

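Expression in 4 preparations of wild-type L4 worms was compared with a wild-type mixed reference on 2-channel arrays. Values were present for 21132, 21084, 21252 and 21489 of the 21632 probes in preparations 1 to 4, and 20466 probes had a value on all 4 arrays. The SD of the log2 ratio over probes was 0.95, 1.19, 1.21 and 0.85 in the same order. The only comparison the labels imply is L4 against the reference. Positive log2 ratios are likely higher in L4, as the direction is not stated, and "higher" and "lower" below carry that limit.

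The named genes with the highest ratios included cuticle collagens, UDP-glucuronosyltransferase genes and 3 irg genes. The highest of the named genes was irg-5 (F35E12.5), an infection response gene, at 6.53 ± 0.31 (SE, n = 4), a 92.1-fold difference with values from 5.85 to 7.46. It was followed by the cuticle collagen col-120 at 5.39 ± 0.38, the cytochrome P450 gene cyp-35A5 at 5.22 ± 0.63, and the collagens col-60 at 5.09 ± 0.40 and col-138 at 5.07 ± 0.29. The infection response genes irg-4 and irg-8 were higher by 4.91 ± 0.34 and 4.09 ± 0.29. The UDP-glucuronosyltransferase genes ugt-8 and ugt-63 were higher by 4.66 ± 0.21 and 3.92 ± 0.43. Also among the highest were pud-2.1 at 4.69, pud-4 at 3.98, dao-4 at 3.89, the peroxisomal acyl-CoA oxidase gene acox-1.2 at 3.82, the transthyretin-related gene ttr-14 at 3.77 and dod-19 at 3.67.

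Other collagens were among the named genes with the lowest ratios. The collagen col-36 (C27H5.5) was lowest at -5.20 ± 0.28 (SE, n = 4), a 36.9-fold difference, with col-84 at -4.70 ± 0.26, col-158 at -4.14 ± 0.28 and the cuticlin gene cut-1 at -4.58 ± 0.39. The caveolin gene cav-1 was at -4.46 ± 0.25, the antimicrobial peptide gene cnc-2 at -4.10 ± 0.32 and the small heat shock gene hsp-12.6 at -4.06 ± 0.39. The fatty acid and retinol binding gene far-7 was at -3.87, the collagen gene dpy-17 at -3.72, the acyl-CoA synthetase gene acs-2 at -3.65, ule-1 at -3.59 and dod-3 at -3.54. The genes T22F3.11, T28A11.19, C53B7.3 and C10G8.4 were at -4.96, -4.15, -3.92 and -3.91. By the rule for naming, these highest and lowest genes have 1 sign on all 4 arrays and include at most 3 of a symbol stem in each direction. Their adjusted p in limma ran from 0.000131 for ugt-8 to 0.00176 for acs-2.

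**Figure D1:**
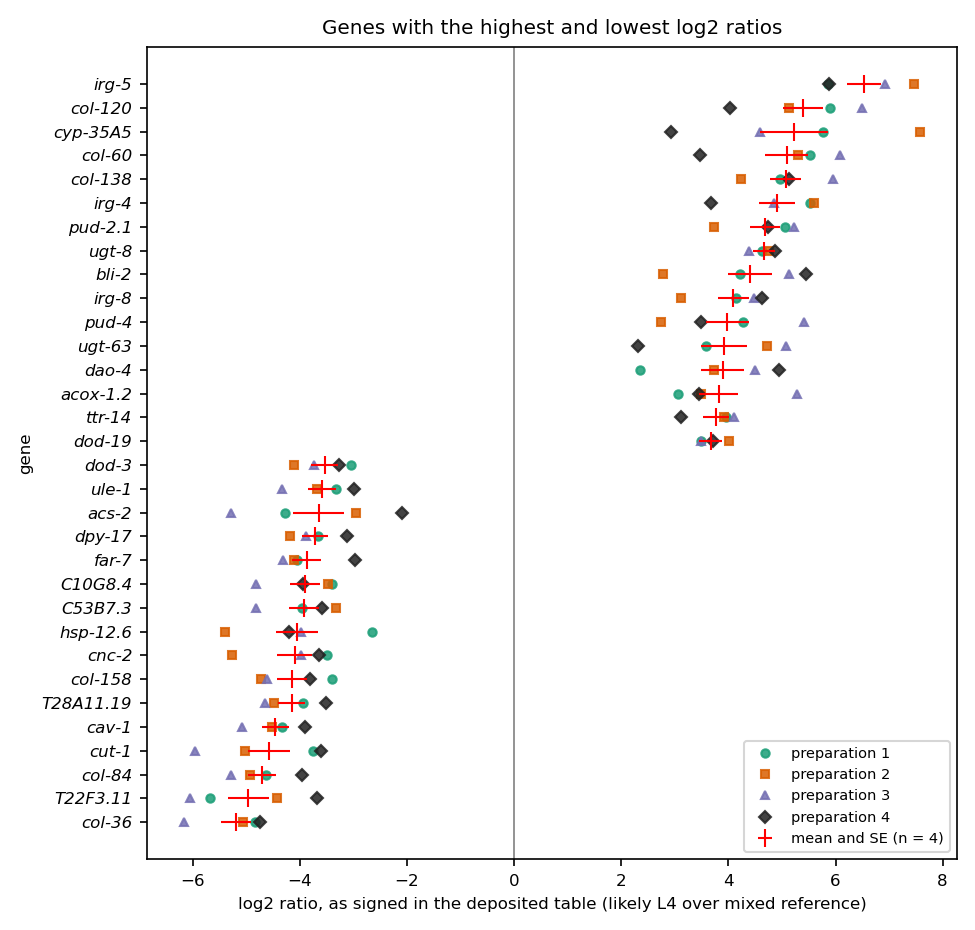
Log2 ratios of the 16 genes named for high and the 16 named for low means, 1 point per preparation, with the mean and its SE in red. Genes were chosen among those with 1 sign on all 4 arrays and at most 3 of a symbol stem in each direction, which leaves out collagens such as col-63 at 4.16, and the means run from 6.53 for irg-5 to -5.20 for col-36.

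In all, 4319 of 19910 probes and genes (21.7%) differed from the reference in limma, 2373 higher and 1946 lower. Of these, 3438 were named genes, 1998 higher and 1440 lower, and 1598 and 1035 of them had a mean of at least 1 in size. Over all named genes tested, 13.4% were called higher and 9.7% lower, the shares to hold list counts against. Without preparation 3 the total was 2406. With each array centred on housekeeping genes, a choice made after the data were seen, it was 2645, with 1233 higher and 1412 lower.

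Most sperm genes measured were higher in L4. Of 30 major sperm protein genes, which encode the cytoskeletal protein of nematode sperm, 29 were higher and 0 lower, and the same numbers passed when adjusted over the list alone. The exception, msp-38, named after its values were seen, was at -0.40 (adjusted p = 0.218). The list median was 2.56, with msp-77 at 2.94 ± 0.46 (SE, n = 4), msp-36 at 2.89 ± 0.42 and msp-64 at 2.82 ± 0.42. Of 59 other sperm and spermatogenesis genes, 45 were higher and 0 lower, or 52 and 0 adjusted over the list alone, with a median of 2.06, sss-2 at 3.03 ± 0.40 and smz-2 at 2.86 ± 0.30. The camera adjusted p was 3.39e-14 for the major sperm proteins and 2.33e-20 for the other sperm genes, and each was 0.661 with an estimated correlation. That correlation was 0.95 for the major sperm proteins, so their counts are far from independent. Without preparation 3, 20 major sperm proteins and 36 other sperm genes were higher, and with housekeeping centring 28 and 36 were. The 4 preparations differed in size. The median of the major sperm proteins was 3.52, 3.53, 2.03 and 1.12 in preparations 1 to 4, and that of the other sperm genes 2.1, 2.65, 1.87 and 1.06.

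Some yolk, oocyte and eggshell genes were lower in L4, and their ratios differed widely between preparations. The yolk genes vit-5 and vit-2, which encode vitellogenins, were at -3.18 ± 0.58 and -2.83 ± 0.62 (SE, n = 4). The third, vit-6, measured on 3 arrays and named after its values were seen, was at -2.29 and did not pass over all genes. All 3 passed when adjusted over the list alone. The yolk median was -2.22, -0.73, -3.33 and -5.28 in preparations 1 to 4. Of 29 oocyte and eggshell genes, 11 were lower and 0 higher, or 20 and 0 adjusted over the list alone, with a median of -1.32. Examples were the eggshell gene perm-2 at -2.55 ± 0.51 and the oocyte genes pos-1 at -2.42 ± 0.54 and oma-2 at -2.26 ± 0.51. The median of this list was -0.89, -0.01, -2.62 and -2.16 in preparations 1 to 4. The camera adjusted p was 0.018 for yolk and 1.18e-07 for oocyte and eggshell genes, and each was 0.661 with an estimated correlation. Without preparation 3, 0 yolk and 0 oocyte genes passed in limma, although 2 and 10 had an unadjusted p under 0.05, and the yolk list did not pass camera (adjusted p = 0.0527). Without preparation 4, 2 oocyte genes passed, and without preparation 2, 24 did.

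**Figure D2:**
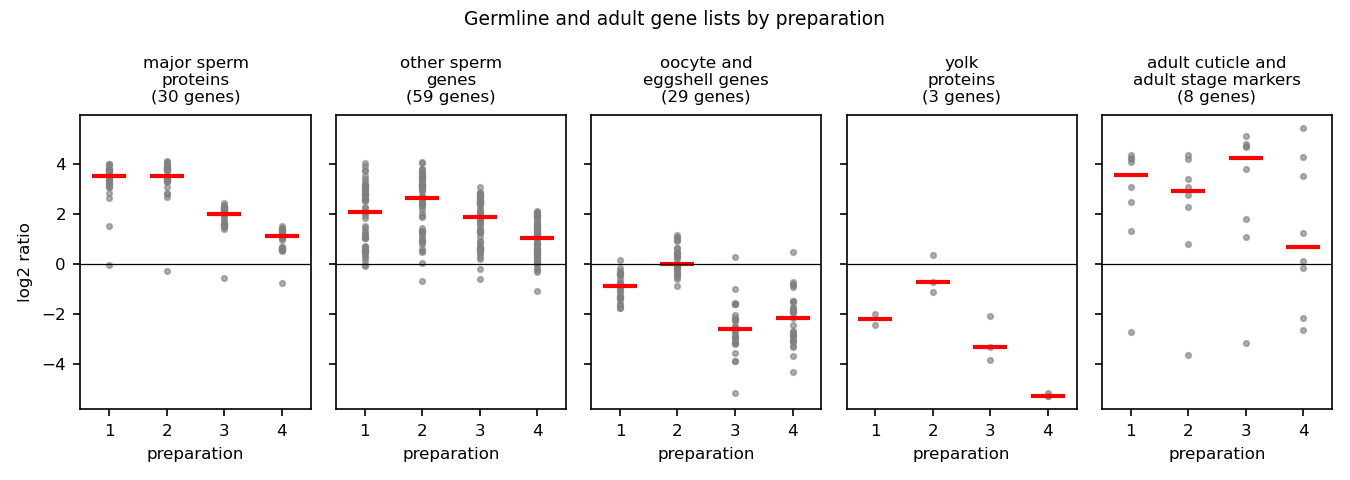
Log2 ratio of each gene (grey) and the median of the list (red) in each preparation for sperm, oocyte, yolk and adult cuticle lists. The major sperm protein median falls between 1.12 in preparation 4 and 3.53 in preparation 2, and the yolk median between -5.28 in preparation 4 and -0.73 in preparation 2.

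DNA replication genes and general germline genes had few members past the threshold. Of 43 DNA replication and mitosis genes, 3 were lower and 0 higher, and 0 passed when adjusted over the list alone. The ribonucleotide reductase gene rnr-2 was at -1.25 ± 0.32 (SE, n = 4) and zyg-11 at -1.04 ± 0.28, and the third, cyb-3, named after its values were seen, was at -1.48. The list passed camera (adjusted p = 0.0134), with 0.996 as the adjusted p with an estimated correlation. Its median was -0.28, 0.51, -1.06 and -0.51 in preparations 1 to 4, and without preparation 3 it did not pass (adjusted p = 0.519). The count of 3 was 10 without preparation 2, 1 without preparation 1 and 0 without preparation 3 or 4, and rnr-2 and zyg-11 had adjusted p of 0.0686 and 0.118 without preparation 3. Of 37 germ granule, germline stem cell and meiosis genes, 1 was higher, the germ granule helicase gene glh-1 at 0.99 ± 0.27, and 0 passed adjusted over the list alone. glh-1 did not pass without preparation 1, 2 or 4 (adjusted p = 0.0994, 0.113 and 0.106), and glh-4, at 0.81, did not pass with all 4 arrays. That list did not pass camera (adjusted p = 0.5), but it did without preparation 2 (adjusted p = 0.0117, lower). With an estimated correlation, run after the data were seen, that adjusted p was 0.99.

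Cuticle collagens moved in both directions. Of 152 measured, 66 were higher, 21 lower and 65 did not pass, or 71 and 27 adjusted over the list alone. The median was 0.73, and the camera adjusted p was 6.77e-05, with an adjusted p of 0.661 with an estimated correlation. Without preparation 3, 43 were higher. Of 8 adult cuticle and adult stage markers, 6 were higher and 1 lower, also when adjusted over the list alone. The collagen genes bli-2, col-63, bli-1 and col-62 were higher by 4.40 ± 0.41, 4.16 ± 0.26, 3.37 ± 0.23 and 3.35 ± 0.69 (SE, n = 4). The member that was lower, fil-1, a lipase gene named after its values were seen, was at -2.92. The list median was 3.58, 2.93, 4.25 and 0.68 in preparations 1 to 4. Its camera adjusted p was 0.00149, and the adjusted p with an estimated correlation was 0.661. With housekeeping centring or without preparation 3, 4 of the markers were higher. Without preparation 3, col-62 did not pass (adjusted p = 0.0827, against a range of 0.00126 to 0.0827 over its alternatives).

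Most dauer and early larva markers were lower. Of 12 measured, 7 were lower and 0 higher, or 9 and 0 adjusted over the list alone, with a median of -1.51. Besides cut-1 and hsp-12.6, the small heat shock gene hsp-12.3 was at -3.49 ± 0.22 (SE, n = 4) and scl-1 at -2.31 ± 0.46. For this list the camera adjusted p was 1.6e-05, and the adjusted p with an estimated correlation was 0.661. Without preparation 3, 5 of the 12 were lower, and without preparation 4, 6 were. Of 23 moulting genes, 3 were higher and 3 lower over all genes and over the list alone, with the metalloprotease gene nas-36 at 1.86 ± 0.28, cut-2 at 1.75 ± 0.38, let-413 at -1.12 ± 0.31 and cut-3 at -3.47 ± 0.32. This list did not pass camera (adjusted p = 0.874), and without preparation 3 cut-2 and let-413 did not pass in limma (adjusted p = 0.0728 and 0.137). Nor did these 2 genes without preparation 4 (adjusted p = 0.0595 and 0.123) or with housekeeping centring (0.0659 and 0.0551). Without preparation 3 or with housekeeping centring, 1 moulting gene was higher and 1 lower, and without preparation 4, 1 was higher.

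Most neuropeptide genes were lower in L4. Of 75 genes of the flp and nlp families, 55 were lower and 2 higher, or 58 and 3 adjusted over the list alone, with a median of -1.32. Those lower included nlp-12 at -2.72 ± 0.28 (SE, n = 4), flp-15 at -2.67 ± 0.27 and nlp-29 at -2.59 ± 0.26, the last encoding an antimicrobial peptide of the epidermis. Those higher, named after their values were seen, were nlp-4 at 1.55 and nlp-22 at 1.11. Without preparation 2 or 3 or with housekeeping centring, 1 was higher, and without preparation 4, 3 were. The 55 lower were 43 without preparation 3, 47 without preparation 2, 49 with housekeeping centring and 52 without preparation 1 or 4. Of 31 neuronal synaptic genes, 11 were lower and 0 higher, or 15 and 0 adjusted over the list alone, with a median of -0.56. The neuropeptide processing genes egl-3 and egl-21 were at -1.79 ± 0.24 and -1.56 ± 0.27, and the synaptic gene ric-4 was at -1.59 ± 0.26. The camera adjusted p was 7.22e-18 for neuropeptides and 4.36e-06 for synaptic genes, and each was 0.661 with an estimated correlation. Without preparation 3, 5 of the synaptic genes were lower, and without preparation 1 or 2, 7 were.

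Some muscle structure genes were higher. Of 39 measured, 14 were higher, 0 lower and 25 did not pass, or 19 and 0 adjusted over the list alone, with a median of 0.63. Examples were dim-1 at 1.71 ± 0.22 (SE, n = 4), the perlecan gene unc-52 at 1.58 ± 0.22, the titin-like gene ttn-1 at 1.55 ± 0.25 and the myosin heavy chain gene myo-3 at 1.5 ± 0.23. The camera adjusted p was 6.77e-05 and the adjusted p with an estimated correlation was 0.661. Without preparation 1 or without preparation 4, 9 genes were higher, and with housekeeping centring 8 were.

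Detoxification genes were higher more often than lower. Of 160 cytochrome P450, glutathione transferase and UDP-glucuronosyltransferase genes, 59 were higher and 10 lower, or 67 and 16 adjusted over the list alone, with a median of 0.50 and ugt-22 at 3.29 ± 0.25 (SE, n = 4). In camera the adjusted p was 3.24e-06, and the adjusted p with an estimated correlation was 0.558. With housekeeping centring 36 were higher, and without preparation 2, 6 were lower. Of 201 C-type lectin genes, 37 were higher and 17 lower, or 42 and 20 adjusted over the list alone. clec-52 and clec-57 were at 3.35 ± 0.23 and 2.94 ± 0.30, and clec-97 and clec-264 at -2.62 ± 0.30 and -2.57 ± 0.24. The lectin list passed camera (adjusted p = 0.0187), with an adjusted p of 0.661 with an estimated correlation, and did not pass without preparation 3 (adjusted p = 0.152), when 24 were higher. With housekeeping centring 21 were higher.

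Of 1047 chemoreceptor genes, 63 were higher and 7 lower, and 0 passed when adjusted over the list alone. Both are smaller shares than the 13.4% and 9.7% over all named genes, so the list was not rich in called genes. The largest of those that passed with 1 sign on all 4 arrays were sra-38 at 3.33 ± 0.74 (SE, n = 4), srab-3 at 2.52 ± 0.75, srb-13 at 2.40 ± 0.38 and str-180 at 2.29 ± 0.39. The list median was 0.22, 0.34, 0.80 and -0.02 in preparations 1 to 4. The list had a camera adjusted p of 2.75e-06, and the adjusted p with an estimated correlation was 0.782. The count of 63 was 9 without preparation 3, 20 without preparation 2, 37 without preparation 1 and 110 without preparation 4. It was 6 with housekeeping centring, and the 7 lower were 15 with values as deposited, 4 with housekeeping centring and 3 without preparation 1 or 2. Without preparation 3, sra-38 and srab-3 did not pass (adjusted p = 0.0908 and 0.121). In limma srab-3 also did not pass without preparation 2 (adjusted p = 0.12), with housekeeping centring (0.138) or under robust shrinkage (0.0992).

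The other 12 lists did not pass camera, with adjusted p from 0.0915 for embryonic genes to 0.987 for core histones. Of 56 embryonic genes, 3 were higher and 6 lower, or 3 and 4 adjusted over the list alone, with pes-8 at 2.5 ± 0.21 (SE, n = 4), pes-9 at 1.52 ± 0.21, hch-1 at -1.74 ± 0.33 and pal-1 at -1.23 ± 0.24. The 6 lower were 2 without preparation 1 and 3 without preparation 2, without preparation 4 or with housekeeping centring. Of 55 histone genes, 3 were higher and 3 lower, or 3 and 2 adjusted over the list alone, among them his-70 at 2.59 ± 0.30 and his-24, a linker histone gene, at -2.29 ± 0.33. Without preparation 2 or 3, 1 was lower, and with housekeeping centring 1 was higher. Of 73 intestinal genes, 17 were higher and 12 lower, or 20 and 14 adjusted over the list alone, with the cathepsin B-like genes cpr-5 at 2.76 ± 0.30 and cpr-2 at -2.82 ± 0.28, the ferritin gene ftn-1 at -3.24 ± 0.29 and the lysozyme gene lys-3 at -3.11 ± 0.23. Without preparation 3, 7 of the intestinal genes were lower. Of 69 hedgehog-related and patched-related genes, 8 were higher and 12 lower, or 15 and 12 adjusted over the list alone, with grd-14 at 2.81 ± 0.39, wrt-6 at 2.68 ± 0.28 and grl-20 at -3.27 ± 0.29. The 8 higher were 18 without preparation 2, above the number lower, 4 without preparation 3 or with housekeeping centring, and 5 without preparation 1 or 4. Of 235 nuclear hormone receptor genes, 15 were higher and 23 lower, or 11 and 20 adjusted over the list alone, with nhr-21 at -2.29 ± 0.24 and nhr-57 at -2.03 ± 0.21. These counts were 5 and 6 without preparation 3, 7 and 10 without preparation 1, 8 and 12 without preparation 2, 7 and 15 without preparation 4, and 3 and 13 with housekeeping centring.

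Of 23 heat shock genes, 4 were higher and 4 lower, or 5 and 5 adjusted over the list alone, including hsp-4, an endoplasmic reticulum chaperone gene, at 1.48 ± 0.24 (SE, n = 4). With housekeeping centring or without preparation 1, 2 were higher and 2 lower, and 2 were higher without preparation 2 or 4 and with values as deposited. Of 12 heterochronic genes, which time larval development, 1 was higher and 1 lower over all genes and over the list alone: mab-10 at 0.85 ± 0.24 and hbl-1 at -2.23 ± 0.36. Of 27 vulva, uterus and somatic gonad genes, 2 were higher and 1 lower on both counts, the hemicentin gene him-4 at 1.55 ± 0.27, gon-1 at 1.20 ± 0.26 and sqv-8 at -0.97 ± 0.24. Of 10 male markers, 1 was lower, cwp-4 at -0.89 ± 0.23, and 0 passed adjusted over the list alone. swm-1 was at -0.70 and did not pass, but it did with values as deposited and with arrays scaled to one spread (adjusted p = 0.0428 and 0.0427). Without preparation 3, mab-10, gon-1, sqv-8 and cwp-4 did not pass (adjusted p = 0.08, 0.0559, 0.0668 and 0.0777), and mab-10 did not pass without any 1 of the 4. sqv-8 also did not pass without preparation 1 or 4 (adjusted p = 0.0723 and 0.053), nor cwp-4 without preparation 1 or 2 (adjusted p = 0.154 and 0.0888). With housekeeping centring mab-10, gon-1 and cwp-4 did not pass (adjusted p = 0.093, 0.0796 and 0.0654). Without preparation 4, 2 heterochronic genes were lower. The median, the mean and the camera direction differed in sign for heat shock genes (median 0.03, mean -0.18, lower) and male markers (median 0.11, mean -0.03, lower). For nuclear hormone receptors the median was 0.02 and the mean 0.01, while camera's direction was lower.

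Housekeeping genes showed few changes. Of 52 ribosomal protein genes, 0 were higher and 0 lower in limma, over all genes or over the list alone, and 1 had an unadjusted p under 0.05. The largest of them in size were rpl-32 at -0.59 and rpl-11.1 at 0.47, neither of which passed. Of 32 oxidative phosphorylation genes, 2 were higher, or 1 adjusted over the list alone, the cytochrome c gene cyc-2.2 at 2.66 ± 0.22 (SE, n = 4) and ucr-2.2 at 0.86 ± 0.22. Without preparation 1, 2 or 4, ucr-2.2 did not pass (adjusted p = 0.0937, 0.0727 and 0.0922). Of 31 proteasome subunit genes, 1 was higher on both counts, rpn-6.2 at 1.13 ± 0.23, and rpn-1 at 0.58 did not pass. The median of these 115 genes together was 0.21, 0.17, -0.50 and 0.40 in preparations 1 to 4. Without preparation 3 all 3 lists passed camera as higher, with adjusted p of 0.00661, 0.00498 and 0.00225 for ribosomal, oxidative phosphorylation and proteasome genes. With an estimated correlation, run after the data were seen, these were 0.849, 0.82 and 0.82 without preparation 3, and each was 0.996 with all 4 arrays.

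**Figure D3:**
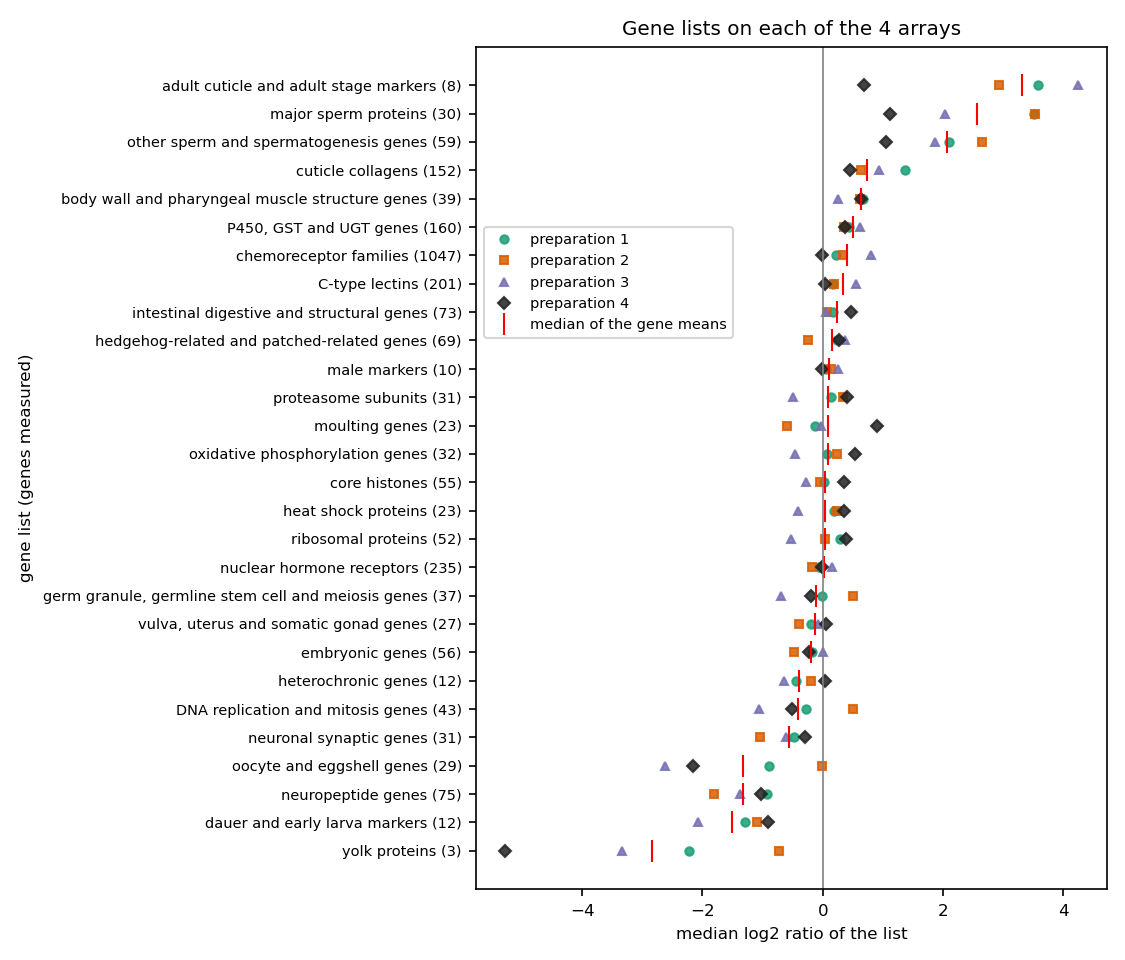
Median log2 ratio of each of the 28 gene lists in each preparation (points) and the median over genes of their mean (red), with the number of genes measured in brackets. Major sperm proteins lie at 1.12 to 3.53 and yolk proteins at -5.28 to -0.73, while ribosomal proteins lie at -0.52 to 0.38.

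No pair of arrays correlated below 0. Across 19101 probes and genes with a value on all 4 arrays, which are not independent replicates, Pearson's correlation was 0.73 between preparations 1 and 2, 0.71 between 1 and 3, 0.66 between 1 and 4, 0.62 between 2 and 3, 0.56 between 2 and 4 and 0.60 between 3 and 4. With the called genes left out these were 0.36, 0.39, 0.30, 0.24, 0.15 and 0.19. All arrays carry the same kind of reference RNA in the same channel, which can by itself give correlations above 0, and the size of that part was not estimated. The median SD between arrays was 0.46. The genes that varied most between preparations were srbc-48, Y69E1A.1, fbxb-115, C08G5.3, M70.2 and srx-62, with SDs of 4.09, 3.59, 3.55, 3.55, 3.53 and 3.37. None of these 6 passed in limma, with adjusted p from 0.115 to 0.957.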

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

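Of 146 results with 4 values each, 6 had a preparation set apart from the other 3 by Dixon's ratio, where chance gives about 1 in 20, or 7.3. So did 4 of the 6 genes named for the highest SD between arrays, to which that rate does not apply because they were picked for their spread. The tests of the reference RNA and of the compression of preparation 4 over genes called without it and over yolk genes were chosen after the results were seen. The other tests in this part were set down before their results.

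Those 4 genes each had 1 high value. The chemoreceptor genes srbc-48 and srx-62 stood at 8.69 and 7.13 in preparation 3, with 1.36 and 0.60 as the highest of the other 3 values. The F-box gene fbxb-115 stood at 7.55 in preparation 3, with 1.07 as the highest of the others. M70.2 stood at 7.94 in preparation 2, with the others from 0.41 to 1.27. The muscle list had a median of 0.25 in preparation 3, against 0.62 to 0.67, but with housekeeping centring preparation 3 was highest, at 0.74 against 0.23 to 0.46. The gene sqv-8 was at -1.66 in preparation 3, against -0.81 to -0.65, and lys-3 at -3.71 in preparation 2, against -2.96 to -2.83. In preparation 4, col-62 was at 0.12 against 4.09 to 4.82, hsp-12.3 at -3.02 against -3.71 to -3.60, and hbl-1 at -0.74 against -2.82 to -2.58.

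The preparations differed in sperm, oocyte, yolk and adult cuticle genes. Compressed ratios on the array of preparation 4 are argued against as the only cause. Its slope on the mean of the other 3 was 0.70 over 4107 other called genes. That is 0.34 above the median ratio of 0.37 for major sperm proteins (bootstrap over genes 0.30 to 0.45). Over 3426 genes called without preparation 4 the slope was 0.63 and the difference 0.26 (0.22 to 0.37). The bootstrap took genes as independent, though the sperm proteins had an estimated correlation of 0.95, so both ranges are too narrow. The yolk median was lowest in preparation 4, by -1.95 from the next, for 3 of 3 yolk genes. Some compression stays open, as both slopes were below 1 and the SD over probes was lowest in preparation 4, at 0.85. Different developmental age of the worms stays open: 68 further maternal genes were higher in preparation 2 than in 4 by 0.57 with housekeeping centring, above the 0.3 set beforehand, but their medians of -0.31, 0.25, 0.00 and -0.32 in preparations 1 to 4 did not follow the full order predicted. Reference RNA that differed between arrays stays open too, since the difference of 4.78 between the yolk medians of preparations 2 and 4, which are -0.90 and -5.68 with housekeeping centring, cannot be assigned to a channel, and no biological difference between preparations is given by the labels.

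Chemoreceptor genes lay above 0 on some arrays only. Their medians were 0.22, 0.34, 0.80 and -0.02 in preparations 1 to 4, and 0.01, 0.16, 1.30 and -0.43 with housekeeping centring. No biological explanation was tested. An offset of weakly expressed genes that differs between arrays may account for the pattern and stays open. The medians of 256 F-box genes were 0.05, -0.16, 0.21 and -0.09 in preparations 1 to 4, and the difference of 0.297 between preparations 3 and 4 fell just under the 0.3 set beforehand. With housekeeping centring it was 1.19, of which 0.90 is added to every gene alike, so that value does not set weakly expressed genes apart.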

How the results depend on the processing

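Centring on housekeeping genes, estimating correlations without 1 array or for genes on all 4 and averaging the arrays of preparations 1 and 4, whose titles share a letter code of unstated meaning, were chosen after the data were seen. The titles also end in what read as dates, not explained either, and that of preparation 4 is the earliest. A difference between dates cannot be told apart from one between preparations. None of the 110 named genes and 14 lists that passed changed sign in any alternative run. With probes kept apart, only the probe with the lowest p of each named gene was compared. Signs of the other called probes and genes were not compared. The counts of 4319 different, 2373 higher and 1946 lower stayed within 1.5 times under values as deposited, scaled arrays, both other minimum numbers of arrays, separate probes, robust shrinkage and averaged arrays, at 3729 to 4632 in total. Tested against a 1.5-fold change they were 1426, 918 and 508, and at a threshold of 0.01 they were 1909, 1141 and 768, both stricter by construction. With housekeeping centring they were 2645, 1233 and 1412, and 2626 of the 2645 were also called with median centring. The centrings differ only by a constant for each array, 0.21, 0.17, -0.50 and 0.40 in preparations 1 to 4. The change in counts comes from these offsets, while the median over probes and genes of the mean log2 ratio moved only from 0.02 to -0.06. Which centring is nearer the truth was not tested. Leaving out 1 array gave 2406 to 3647 different, 1395 to 2162 higher and 1011 to 1485 lower, lowest without preparation 3 each time. Fewer arrays tend to lower the counts, but some list counts rose. Chemoreceptor genes higher went from 63 to 110 without preparation 4, and oocyte genes lower from 11 to 24 without preparation 2. The number of arrays does not explain why the counts were lowest without preparation 3. Of the 28 lists, 14 passed camera, 0 with estimated correlations (all 4 arrays or any 3), 5 with fry, and 14 to 15 without 1 array. Those 5 were other sperm, adult cuticle, dauer, neuropeptide and detoxification genes. The 0 with estimated correlations does not by itself show whether correlated genes made the shifts. Detoxification genes failed that test too, at an estimated correlation of 0.01, the preset value. With all 4 arrays the estimate was 0.95 for major sperm proteins and 0.96 for yolk, so for those lists correlated genes stay open. Under robust shrinkage lectins, DNA replication and yolk did not pass, at 0.0548, 0.0548 and 0.0686; that setting ranked moderated statistics with cameraPR, so the change may come from the other test. Embryonic genes passed when measured on all 4 arrays (0.0453) and without preparation 3 (0.0199), and heterochronic genes without preparation 4 (0.0413), but with estimated correlations these were 0.684, 0.728 and 0.737. Of 110 named genes that passed, 81 passed under all 14 alternatives and 29 lost the call under at least 1, 22 of them without preparation 3. These include vit-5 (adjusted p = 0.0605, range 0.00391 to 0.0605), vit-2 (0.0936, range 0.0071 to 0.0936), perm-2 (0.0744, range 0.00578 to 0.0744) and sra-38 (0.0908, range 0.000305 to 0.0908). The median correlation between arrays was 0.64, and 0.27 with called genes left out, or 0.32 by Spearman; leaving out genes called for a shared shift lowers it by construction. A title code as a random block could not be fitted with 3 codes over 4 arrays and was not run, and the X chromosome comparison was not made. No paired analysis was possible because there is only 1 group. Spot signal over background was not used here, so weak spots could not be weighted.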

Other observations

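Families outside the 28 lists were compared after the data were seen, by Fisher's exact test (one-sided) of 101 symbol stems with at least 10 members, in both directions, adjusted over 202 tests. Genes are not independent replicates, and close family members may share probes' signal. Of 13 abu genes, 12 were higher (adjusted p = 7.56e-08, median 1.77), against 13.4% of all named genes, with abu-15 at 2.38 ± 0.39 (SE, n = 4) and abu-1 at 2.37 ± 0.37. Their median was 1.73, 2.48, 2.57 and 0.78 in preparations 1 to 4. Of 12 acyl-CoA dehydrogenase genes of the acdh stem, 7 were higher (adjusted p = 0.0095), with acdh-1 at 3.33 ± 0.22 and acdh-8 at 2.63 ± 0.29.

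Families with more genes lower than the 9.7% of all named genes included Skp1-related genes, of which 11 of 16 were lower (adjusted p = 1.85e-06), with skr-9 at -2.62 ± 0.27 (SE, n = 4) and skr-8 at -2.58 ± 0.28. Of 20 insulin-like genes, 9 were lower and 2 higher (adjusted p = 0.00181), with ins-35 at -1.97 ± 0.24 and ins-17 at -1.94 ± 0.21. Of 45 transthyretin-related genes, 16 were lower and 3 higher (adjusted p = 0.000115), with ttr-50 at -3.31 ± 0.21 and ttr-14 at 3.77 ± 0.24. Of 41 nssp genes 17 were lower (adjusted p = 5.45e-06), and of 23 pals genes 9 were lower (adjusted p = 0.00562), with pals-39 at -2.34 ± 0.32.

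The sign of the ratios was tested after the values were seen. Ratios written as reference over L4 would put sperm genes, made in L4 hermaphrodites, below 0. They would put yolk genes, made by adults, above 0 if the reference held adult RNA, which is not stated. Instead 29 of 30 major sperm proteins lay above 0 and 3 of 3 yolk genes below, which argues against that direction, so positive values are likely higher in L4. Adult cuticle and adult stage markers were not part of this test: 6 of 8 were higher, with a median of 3.32. Their name does not say at which stage they are transcribed, so they do not decide the sign. The conclusion rests on known timing of sperm and yolk production, not on a label. As it uses the sperm and yolk values themselves, their direction in the results is not a separate finding.

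Single arrays held isolated extreme values. In 76 probes and genes the ratio was above 4 on 1 array and below 2 on the other 3, of which 13, 36, 27 and 0 were on preparations 1 to 4. In 13 it was below -4 on 1 array and above -2 on the others, with 9 on preparation 3 and 4 on preparation 4. The adult collagens col-19 and col-7, named after their values were seen, met neither limit. They were at 2.47, 2.27, 1.08 and -2.65, and at 4.38, 4.20, 4.74 and -0.16, in preparations 1 to 4. Both were lowest in preparation 4, as was the median of adult cuticle and adult stage markers, at 0.68.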
